A study of Mus musculus with 17 samples.

How the data were processed

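Total RNA from sorted mouse bone marrow cells was measured on 17 Affymetrix expression arrays, each holding 45101 probe sets. Per the labels' protocols, marrow from femurs and tibias was stained with a fluorescein-labelled mixture of antibodies to CD24, CD48 and Gr-1, which are markers attached to the cell surface by a glycosylphosphatidylinositol (GPI) anchor, and a cell sorter separated GPI-deficient from GPI-normal cells. For transplantation, marrow cells of Pig-a knock-out donors were kept for 30 minutes with 10 nM aerolysin, a bacterial toxin that lyses cells bearing GPI-anchored proteins, and the enriched GPI-deficient cells were given to C57BL/6 recipients irradiated with 9 Gy. RNA was extracted with a column kit and biotin-labelled by the manufacturer's protocols. The protocols state an input of 500 ng RNA for the first experiment and 1000 ng for the second, which were taken here to be batches 1 and 2 of the sample titles, although the labels do not say so outright. The titles call the arrays of a group biological replicates and do not name the animals, so p-values measure the spread between these arrays.

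The authors' deposited value table was used for all comparisons. Its values are on a log10-like scale from 0 to 3.857 in batch 1 and to 3.895 in batch 2, with array medians of 0.515 and 0.387. The base was read from the values, since it is not given in the sources used here. Across the bacterial and phage control transcripts added at hybridisation, with nominal concentrations of 1.5, 5, 25 and 100 pM, the deposited value rose with log10 concentration with a slope of 1.06 ± 0.119 (SD, n = 6 arrays) in batch 1 and 1.21 ± 0.0453 (n = 11) in batch 2, close to what a log10 intensity would give. The rise was not a straight line, and on each array it was steeper from 25 to 100 pM than from 1.5 to 5 pM. On wild-type replicate 1 the values were 0.970, 1.380, 2.226 and 3.341, and on knock-out GPI-negative replicate 2 they were 2.027, 2.409, 2.965 and 3.629. Fold changes of bright genes may therefore be overstated. The slope differed between groups within the batches, at 0.96 ± 0.07 in knock-out GPI-negative and 1.15 ± 0.01 in GPI-positive samples, and at 1.19 ± 0.01, 1.17 ± 0.02 and 1.26 ± 0.03 in recipients of knock-out marrow, recipients of wild-type marrow and wild type. Towards 0 the values flatten, so differences of dim genes are compressed or distorted and a fold change of a gene near the floor is only approximate. Within each batch the sorted values of all arrays are identical, with a largest difference of 0, which shows that the deposited values were quantile-normalized separately per batch. The background correction and probe summary are not given in the sources used here. GCOS, the manufacturer's array software, is named in the submitters' processing notes without a role.

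The deposited log10 values were divided by the log10 of 2 to give log2 values. Array medians differed between batches by more than 0.1 on the log2 scale, the limit set beforehand, so arrays were centred on a common median. The design fixed beforehand had assumed linear or log2 values, and its rule for log2 values was applied after the conversion. Of the probe sets, 64 controls were left out. By the array platform's annotation, 34945 of the other probe sets carry 1 gene symbol, 932 carry several and 9160 are unnamed here. Symbols were checked through gene identifiers against a RefSeq table of assembly GRCm38.p6, which had 34741 of the probe sets with 1 symbol. No genome was used, so no coordinates are given. A probe set was kept when it reached its array's 40th percentile on at least 3 arrays (32426 probe sets), and the brightest kept probe set with 1 symbol stood for each gene, which left 14245 genes.

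One limma fit (lmFit, then eBayes with an intensity trend) over all 17 arrays estimated 5 group means with 12 residual degrees of freedom. Contrasts were taken within a batch: GPI-negative against GPI-positive cells of knock-out marrow (3 and 3 arrays), GPI-negative cells of recipients of knock-out marrow against GPI-positive cells of recipients of wild-type marrow (4 and 3), the former against wild-type GPI-positive cells (4 and 4), and GPI-positive cells of recipients of wild-type marrow against wild-type GPI-positive cells (3 and 4). The interaction is the difference between the first contrast and the second, which share no array. P-values were adjusted by Benjamini-Hochberg over the 14245 genes, with a threshold of 0.05. Fold changes are 2 to the power of the absolute log2 difference, and errors of log2 differences are the fit's standard errors (SE). The median SE over genes was 0.154 in the first contrast, 0.144 in the second, 0.133 in the third, 0.144 in the fourth and 0.211 in the interaction. The number of arrays per group limits the precision. Single values were also compared by exact two-sided permutation tests of group means.

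Before the data were examined, 30 gene lists were fixed from general knowledge of marrow cell types, GPI biology and stress pathways, and the 28 with at least 5 tested genes, apart from the sex-linked check list, were tested by limma's camera (two-sided, preset correlation 0.01, Benjamini-Hochberg over lists within a contrast). camera with an estimated correlation and fry were run beside it. Some genes stand on several lists, such as Ccl5 (T and NK cell, inflammatory), C1qa (complement, monocyte and macrophage) and Tfrc (erythroid, heme and iron). Lists of functions also hold markers of cell types, such as the T-cell antigen gene Thy1 among the GPI-anchored proteins. Calls of different lists are therefore not independent and need not be separate changes. The sort antibody list had 2 tested genes, Cd24a and Cd48, which are reported singly. Named genes follow a rule fixed at the same time: Piga and the sort antibody genes, the 12 largest changes per direction among genes past the threshold whose groups did not overlap, up to 4 members with the smallest p of each list past the threshold and up to 2 of other lists, and the 6 largest interactions per direction. Clone and predicted-gene symbols were counted, not named. Some genes were named after their values were seen, to complete small counts: Zap70, Nkg7, Calr, Ngp, S100a8, S100a9 and Ly86 in knock-out marrow, C1qa, C1qc, Mrc1, Icam1, Itgal, Psmb10, Osm and Hspa1b among transplant recipients, Jund, B2m, Il5ra and Nqo1 in recipients of knock-out marrow against wild type, and Cr2 and Fcer2a in the interaction.

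The fit was tested on simulated normal values with each gene's mean and pooled within-group spread, with 200 of 14245 genes changed. For the knock-out contrast it recovered 89% of genes changed by 1 log2 unit and 23% of those changed by 0.5, and 5.9% of calls were false. For the contrast of transplant recipients the shares were 88%, 25% and 8.1%, for recipients of knock-out marrow against wild type 90%, 33% and 3.1%, and for recipients of wild-type marrow against wild type 92%, 32% and 6.8%. The simulated genes were independent and had the same spread in all groups. The real knock-out groups differed in spread (median SD over bright probe sets 0.181 and 0.064), and 29.5% of genes were called between them. These shares therefore need not hold for the real contrasts.

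Alternatives fixed beforehand were quantile and cyclic loess normalization over all arrays, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, all probe sets separately, only the arrays of a comparison or of its batch, eBayes without trend and with robust estimation, arrayWeights, the replicate number as a block, a 2-fold threshold, an adjusted p of 0.1, and each array left out in turn. Pseudocounts for linear values had no use on these values. A sex covariate was not run, because the Y-linked signal separates the batches and does not vary within any comparison. After the data were seen, a covariate for the Xist level, averaging the 3 knock-out GPI-positive arrays into 1 sample, and leaving out all genes of the cell type lists were added. The tools were R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with matplotlib 3.10.9 for the plots.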

Results

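Bone marrow cells carrying or lacking proteins held at the cell surface by a GPI anchor were profiled in 5 groups on 17 arrays. Piga encodes the catalytic part of the enzyme that makes the first intermediate of the anchor, and its loss leaves cells without GPI-anchored proteins. In batch 1, sorted GPI-negative and GPI-positive marrow cells of Pig-a knock-out mice were measured on 3 arrays each. Batch 2 held GPI-negative cells of irradiated recipients of knock-out marrow (4 arrays), GPI-positive cells of recipients of wild-type marrow (3 arrays) and GPI-positive cells of wild-type mice (4 arrays). The comparisons ask how GPI-negative cells differ from GPI-positive cells in the knock-out and after transplantation, and how recipients of wild-type marrow differ from untreated mice. The recipient groups are different animals that differ in donor genotype as well as in GPI status. The labels give aerolysin and irradiation only for the recipients of knock-out marrow. Between the recipients, GPI status therefore cannot be told apart from the graft and its treatment.

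Piga signal was lower in both GPI-negative groups. On the brighter Piga probe set the deposited log10-like value was 0.61 ± 0.05 (SD) in knock-out GPI-negative cells against 1.22 ± 0.09 in knock-out GPI-positive cells, 3 arrays each. It was 0.11 ± 0.09 in GPI-negative cells of recipients of knock-out marrow (n = 4), 1.20 ± 0.03 in recipients of wild-type marrow (n = 3) and 1.22 ± 0.03 in wild-type cells (n = 4). The differences were 4.11-fold in the knock-out (log2 change -2.04 ± 0.16 SE, adjusted p = 5.8e-09), at least 12.3-fold between the recipients (-3.62 ± 0.15, adjusted p = 1.8e-12) and at least 12.9-fold against wild type (-3.69 ± 0.14, adjusted p = 2.5e-13). In each of these comparisons the groups did not overlap, and the exact two-sided permutation p was 0.1, 0.02857 and 0.02857, in each case the smallest the design allows. GPI-positive cells of recipients of wild-type marrow showed no detectable difference from wild-type cells (-0.07 ± 0.15, adjusted p = 0.88). A second Piga probe set was lower by smaller amounts, with log2 differences of -1.09, -0.71 and -0.86 in the 3 comparisons with GPI-negative cells and an exact permutation p of 0.05714 between the recipients. On the brighter probe set the Piga mean in recipients of knock-out marrow lay at the 6.8th percentile of all probe sets, where the scale flattens and signal cannot be told from background, so the folds of this group are lower bounds for that probe set and their SE does not cover this. In knock-out GPI-negative cells the mean on this probe set was also dim, at the 57.1th percentile, so the knock-out fold may be compressed too. Which part of the gene the knock-out removes is not given in the sources used here.

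**Figure D1:**
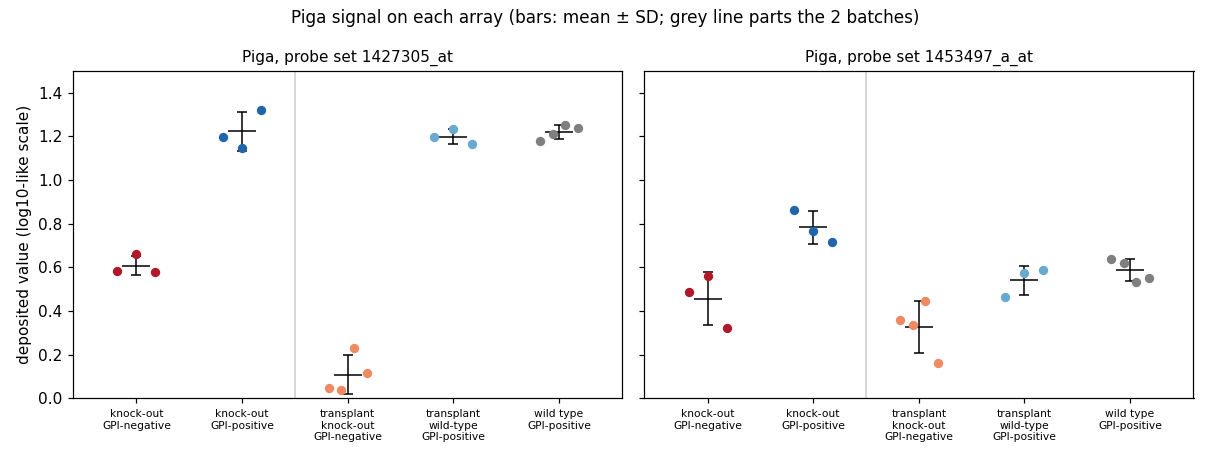
Piga signal on each array by group, on the deposited log10-like scale, for the 2 Piga probe sets, with group means and SD. On the brighter probe set the means are 0.61 and 1.22 in knock-out GPI-negative and GPI-positive cells, 0.11 in GPI-negative cells of recipients of knock-out marrow, and 1.20 and 1.22 in the GPI-positive groups of batch 2.

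The genes behind the sort antibodies moved in different directions. Cd24a, which encodes a GPI-anchored antigen of immature blood cells, fell by 1.11 ± 0.14 on the log2 scale in knock-out GPI-negative cells (adjusted p = 6e-06). However, 1 of its 2 other probe sets was higher, by 0.60. It was also lower in recipients of knock-out marrow than in recipients of wild-type marrow (-0.65 ± 0.14, adjusted p = 0.0041) and wild-type cells (-0.83 ± 0.13, adjusted p = 0.00013). Cd48, a GPI-anchored member of the SLAM family, rose in the same comparisons by 0.75 ± 0.14, 0.71 ± 0.13 and 0.87 ± 0.12. The probe set shared by Ly6c1 and Ly6c2 differed by -1.39 in the knock-out and by 0.08 between the recipients, and it was not tested because it carries several gene symbols. The array annotation used here gives no probe set for Ly6g.

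In knock-out marrow, genes of T and natural killer (NK) cells were among the strongest rises in GPI-negative cells. Of the 24 list genes for these cells tested, 23 rose and Zap70 did not pass. The list median was 2.99 on the log2 scale (camera adjusted p = 3.81e-31, adjusted p = 0.0469 with an estimated correlation; 23 adjusted over the list alone). Trbv1, a T-cell receptor segment, rose 32.9-fold (log2 5.04 ± 0.30 SE, 3 arrays per group, adjusted p = 1.7e-10). Cd8b1, a chain of the CD8 coreceptor, rose 23.6-fold, the chemokine gene Ccl5 22.9-fold, Thy1, which encodes a GPI-anchored T-cell antigen, 19.8-fold and Cd3g, part of the T-cell receptor complex, 15.4-fold. Klrd1, which encodes a subunit of NK receptors, rose 14.4-fold, and Cd28 and Il2rb, a costimulatory receptor and a chain of the interleukin 2 receptor, rose by 2.97 ± 0.16 and 3.03 ± 0.17 log2.

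Further groups rose in knock-out GPI-negative cells. Dendritic cell genes rose in 10 of 16 cases (11 adjusted over the list alone) with a median of 0.88 (adjusted p = 6.41e-06, adjusted p = 0.1 with an estimated correlation). Siglech, a receptor of plasmacytoid dendritic cells, rose 4.99-fold, and Tcf4, the transcription factor that specifies these cells, 2.5-fold. Of 23 B cell genes 13 rose and none fell (15 adjusted over the list alone), with a median of 0.53 (adjusted p = 1.19e-04, adjusted p = 0.469 with an estimated correlation). They included Igll1 and Vpreb1, the surrogate light chain genes of early B cells, 3.59-fold and 3.33-fold, and Rag1, which recombines antigen receptor genes, by 0.85 ± 0.17 log2. Genes of antigen processing and MHC class I rose in 6 of 12 cases (6 adjusted over the list alone) with a median of 0.39 (adjusted p = 1.19e-04, adjusted p = 0.0964 with an estimated correlation). Nlrc5, the transactivator of these genes, rose 4.67-fold and H2-K1, an MHC class I heavy chain, 2.1-fold. Cytosolic ribosomal protein genes rose in 9 of 19 cases (11 adjusted over the list alone; median 0.34, adjusted p = 8.65e-04, adjusted p = 0.239 with an estimated correlation). Rps15 rose by 0.62 ± 0.12.

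Genes of granulocytes and macrophages fell in the same cells. Of 10 neutrophil primary granule genes 8 fell, Nkg7, which NK cells also express, rose, and Calr did not pass. The median was -1.22 (adjusted p = 4.33e-06, adjusted p = 0.0964 with an estimated correlation; 8 lower and 1 higher adjusted over the list alone). Elane, which encodes neutrophil elastase, fell 3.74-fold and Fcnb, a ficolin of granulocytes, 5.67-fold. Of 17 secondary and tertiary granule genes 14 fell and Ngp, S100a8 and S100a9 did not pass (median -1.15, adjusted p = 1.68e-10, adjusted p = 0.0964 with an estimated correlation; 15 adjusted over the list alone). Anxa1, an anti-inflammatory phospholipid-binding protein, was 3.46-fold lower. The eosinophil, basophil and mast cell list fell in 7 of 13 cases (7 adjusted over the list alone; median -0.70, adjusted p = 4.41e-04, adjusted p = 0.239 with an estimated correlation). Prg2, eosinophil major basic protein, fell 8.24-fold, and Epx, eosinophil peroxidase, 3.96-fold. Among 23 monocyte and macrophage genes 11 fell and Irf8 and Ly86 rose, with the same counts adjusted over the list alone (median -0.48, adjusted p = 8.65e-04, adjusted p = 0.347 with an estimated correlation). Vcam1, the adhesion molecule of marrow macrophages and stroma, fell 3.52-fold and C1qa, a chain of complement C1q made by macrophages, 3.4-fold. Complement genes fell in 7 of 15 cases while Itgax rose (7 lower and 1 higher adjusted over the list alone; median -0.36, adjusted p = 0.00176, adjusted p = 0.1 with an estimated correlation), and Itgam, the alpha chain of complement receptor 3, fell 3.07-fold. Cell cycle genes fell in 10 of 26 cases (11 adjusted over the list alone; median -0.30, adjusted p = 8.65e-04, adjusted p = 0.565 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, was 1.69-fold lower. The arrays were not alike in this, as the cell cycle list mean was 5.141 and 5.274 on GPI-negative replicates 1 and 3 but 5.695 on replicate 2, against 5.685 to 5.717 on the GPI-positive arrays. Single genes of antibody-secreting cells were lower, Jchain 8.22-fold and Igha 6.69-fold, while the plasma cell list did not pass (adjusted p = 0.588). None of 21 erythroid genes passed in limma's fit (1 lower at an unadjusted p under 0.05; median 0.01, adjusted p = 0.929). Their list mean was 5.066 and 5.441 on GPI-negative replicates 1 and 3 and 6.308 on replicate 2, below and above the 5.590 to 5.625 of the GPI-positive arrays. Heme and iron genes were spread in the same way, at 5.040 and 5.155 on replicates 1 and 3 and 5.768 on replicate 2 against 5.441 to 5.494. GPI biosynthesis genes, Piga among the lower ones, did not pass as a list in camera (3 higher, 6 lower of 28, adjusted p = 0.437). With fry this list was lower (adjusted p = 0.0183). Genes of GPI-anchored proteins did not pass in camera either (6 higher, 8 lower of 22, adjusted p = 0.437).

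In limma's fit, 4206 of 14245 genes changed between the knock-out fractions, 2102 higher and 2104 lower in GPI-negative cells, and 368 and 381 of them by at least 2-fold. The balance of directions depended on the processing, with 2412 higher and 1843 lower under cyclic loess normalization and 1896 higher and 2341 lower with the mean of a gene's probe sets. The groups did not overlap for 43.2% of genes, where chance gives 10%. Measures of the arrays moved with the groups. Hybridisation controls were 8.80 ± 0.32 (SD, log2) in GPI-negative and 6.98 ± 0.23 in GPI-positive samples. The Gapdh 3' minus 5' signal was -0.16 ± 0.13 against -1.02 ± 0.02, and the slope of the hybridisation controls on log10 concentration 0.96 ± 0.07 against 1.15 ± 0.01. Each had an exact permutation p of 0.1, the smallest the design allows. The 3 GPI-positive arrays lay unusually close together, with a median SD over bright probe sets of 0.064 against 0.181 in GPI-negative cells. Averaging them into 1 sample, an alternative chosen after seeing the data, left 1652 changed genes (835 higher, 817 lower). The lone sample is assumed there to vary like the other groups, from which the spread is taken. In the fit with all arrays 11 of 28 lists passed, 5 higher and 6 lower, and the T and NK cell list was the 1 that also passed with an estimated correlation.

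**Figure D2:**
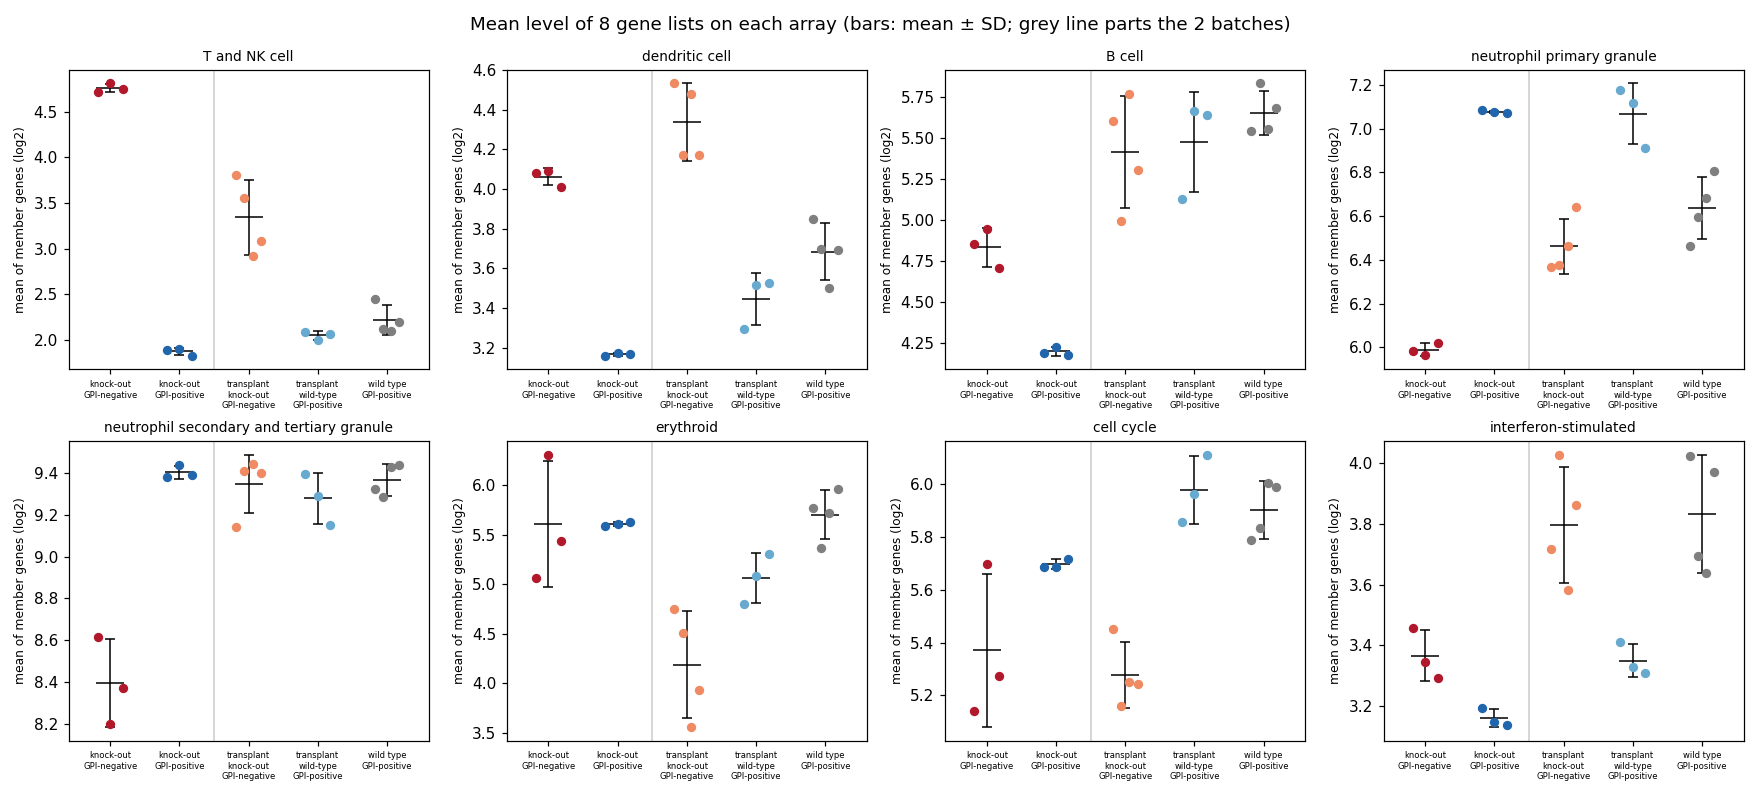
Mean log2 level of the member genes of 8 gene lists on each array, by group, with group means and SD. The T and NK cell list lies at 4.716 to 4.813 on the knock-out GPI-negative arrays and at 1.827 to 1.903 on the GPI-positive ones, and at 2.916 to 3.807 in recipients of knock-out marrow against 1.996 to 2.090 in recipients of wild-type marrow.

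After transplantation, GPI-negative cells of recipients of knock-out marrow also had higher T and NK cell genes than GPI-positive cells of recipients of wild-type marrow, in 20 of 24 cases (21 adjusted over the list alone; median 1.21, adjusted p = 7.36e-29, adjusted p = 0.0266 with an estimated correlation). Ccl5 rose 7.54-fold (log2 2.91 ± 0.28 SE, 4 and 3 arrays, adjusted p = 1.1e-06), Trbv1 6.8-fold, Gimap4, a GTPase of lymphocytes, 5.38-fold, and Thy1 4.45-fold. Klk1, a kallikrein protease gene, rose 6.57-fold, with 2 of its 3 other probe sets in the same direction. Dendritic cell genes rose in 11 of 16 cases (12 adjusted over the list alone; median 0.85, adjusted p = 7.37e-16, adjusted p = 0.0208 with an estimated correlation). Siglech was 4.68-fold and the chemokine receptor gene Ccr9 3.88-fold higher. Of 25 interferon-stimulated genes 14 rose (16 adjusted over the list alone; median 0.49, adjusted p = 1.93e-11, adjusted p = 0.0503 with an estimated correlation). Against untreated wild type the same cells showed no call of this list (median -0.10, adjusted p = 0.811), and the recipients of wild-type marrow were themselves lower than wild type (median -0.46). Irf9, a subunit of the interferon-activated factor ISGF3, was higher between the recipients by 0.57 ± 0.11, and Zbp1, a sensor of nucleic acids, by 0.73 ± 0.17.

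Smaller shifts upward involved inflammatory mediators, of which Ccl3, Ccl5, Ccl9, Osm and Ltb, 5 of 21, rose (11 adjusted over the list alone; median 0.41, adjusted p = 1.89e-08, adjusted p = 0.0307 with an estimated correlation). MHC class I genes rose in 5 of 12 cases, Nlrc5, H2-K1, Psmb8, Psmb10 and Tap1 (10 adjusted over the list alone; median 0.34, adjusted p = 1.72e-07, adjusted p = 0.0266 with an estimated correlation). Nlrc5 rose by 0.95 ± 0.14. Psmb8 no longer passed without replicate 1 or 2 of the recipients of wild-type marrow (adjusted p = 0.0659 and 0.0657). Tap1 no longer passed without replicate 1, 2 or 3 of the recipients of knock-out marrow or 2 or 3 of those of wild-type marrow (0.0518 to 0.192). On the adhesion and homing list Itgb7, Itgal, Selplg, Icam1 and Ccr7 rose and Vcam1 fell, of 19 genes (6 higher and 1 lower adjusted over the list alone; median 0.25, adjusted p = 7.04e-04, adjusted p = 0.0307 with an estimated correlation). Itgb7, an integrin of gut-homing lymphocytes, rose by 1.30 ± 0.15. GPI-anchored protein genes rose in 8 of 22 cases and Cd24a fell (10 higher and 3 lower adjusted over the list alone; median 0.23, adjusted p = 0.00286, adjusted p = 0.0383 with an estimated correlation). Bst2, an interferon-induced tether of viruses, was 3.03-fold and Cd14, the coreceptor for lipopolysaccharide, 1.94-fold higher. Of 26 immediate early and heat shock genes Klf2, Junb, Ier2, Atf3 and Hspa1b rose (11 adjusted over the list alone; median 0.41, adjusted p = 5.42e-06, adjusted p = 0.175 with an estimated correlation). Without replicate 2 of the recipients of wild-type marrow Junb, Ier2 and Atf3 no longer passed (adjusted p = 0.0904, 0.143 and 0.135). The same held for Junb and Atf3 without replicate 3 of that group (0.0751 and 0.0533), for Ier2 without replicate 3 or 4 of the recipients of knock-out marrow (0.0517 and 0.0506) and for Atf3 without replicate 2 or 3 of them (0.058 and 0.0509). Bcl2, the inhibitor of apoptosis, rose 2.67-fold. Its list passed (2 of 22 higher, 4 adjusted over the list alone; median 0.19, adjusted p = 6.46e-04, adjusted p = 0.166 with an estimated correlation). The other member was Mcl1, whose call was lost without replicate 2 or 3 of the recipients of wild-type marrow (adjusted p = 0.0694 and 0.124) or of knock-out marrow (0.0854 and 0.0713). Monocyte and macrophage genes moved both ways, with 10 higher, including Cd68 by 0.96 ± 0.12, and Vcam1, C1qa, C1qb, C1qc and Mrc1 lower. That list passed narrowly (11 higher and 5 lower adjusted over the list alone; median 0.35, adjusted p = 0.0473, adjusted p = 0.541 with an estimated correlation). It missed the threshold with quantile normalization over all arrays (0.064), with the replicate number as a block (0.12), and without replicate 2 (0.14) or 4 (0.097) of the recipients of knock-out marrow or replicate 1 (0.089) or 2 (0.15) of the recipients of wild-type marrow.

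Cell cycle and erythroid genes were lower in recipients of knock-out marrow. Of 26 cell cycle genes 23 fell (25 adjusted over the list alone; median -0.73, adjusted p = 1.1e-26, adjusted p = 0.0307 with an estimated correlation). Cdc20 was 1.81-fold, Nusap1, a spindle protein, 1.8-fold and Top2a, DNA topoisomerase II alpha, 1.66-fold lower. Erythroid genes fell in 11 of 21 cases (15 adjusted over the list alone; median -0.86, adjusted p = 2.07e-11, adjusted p = 0.175 with an estimated correlation). Car1, a carbonic anhydrase of red cells, was 2.7-fold, Rhd, which encodes a Rhesus antigen, 2.75-fold and Klf1, the erythroid transcription factor, 2.55-fold lower. Neutrophil primary granule genes fell in 7 of 10 cases (7 adjusted over the list alone; median -0.63, adjusted p = 4.97e-08, adjusted p = 0.0307 with an estimated correlation), Fcnb 2.95-fold and Elane 2.09-fold. This list did not pass against untreated wild type (median -0.18, adjusted p = 0.189), while recipients of wild-type marrow were higher than wild type (median 0.47). None of the 17 secondary and tertiary granule genes passed in limma's fit (3 higher and 1 lower at an unadjusted p under 0.05; median 0.01, adjusted p = 0.643). Vcam1 fell 3.82-fold. Of 18 heme and iron genes Alad, Tfrc, Blvrb and Abcb10 fell (5 adjusted over the list alone; median -0.33, adjusted p = 3.55e-04, adjusted p = 0.188 with an estimated correlation). Without replicate 3 of the recipients of wild-type marrow these 4 had adjusted p of 0.0746, 0.144, 0.106 and 0.0648. Tfrc, Blvrb and Abcb10 also missed the threshold without replicate 2 of that group (0.109, 0.0835 and 0.0773). Tfrc and Blvrb did so without replicate 3 (0.0908 and 0.0664) or 4 (0.095 and 0.0831) of the recipients of knock-out marrow, and Tfrc without replicate 2 of these (0.0882). Of 14 plasma cell genes Fkbp11 fell (4 adjusted over the list alone; median -0.30, adjusted p = 0.00471, adjusted p = 0.242 with an estimated correlation). This list's call was lost without replicate 2 of the recipients of wild-type marrow (0.062). Fkbp11 missed the threshold without replicate 2 of the recipients of knock-out marrow (0.0989) or 1 (0.107) or 3 (0.0982) of those of wild-type marrow. Its change turned to a log2 change of 0.061 when the mean of its probe sets was used. B cell genes (3 of 23 higher, adjusted p = 0.758), ribosomal protein genes (none of 19 in limma's fit, 1 lower at an unadjusted p under 0.05, adjusted p = 0.736) and p53 target genes (1 of 16 higher, adjusted p = 0.0613) did not pass as lists.

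Between the recipients, 1053 of 14245 genes changed, 562 higher and 491 lower in GPI-negative cells, 101 and 41 of them by at least 2-fold. The groups did not overlap for 15.5% of genes, where chance gives 5.71%. Leaving out replicate 2 or 3 of the recipients of wild-type marrow lowered the count to 680 and 684. Of the 15 lists past the threshold, 10 higher and 5 lower, 8 also passed with an estimated correlation: T and NK cells, cell cycle, dendritic cells, inflammatory mediators, neutrophil primary granule, MHC class I, adhesion and GPI-anchored proteins. Against untreated wild type 9 of the 15 passed in the same direction and 6 did not pass. Of these, interferon-stimulated genes had 3 higher and 2 lower of 25, primary granule genes 2 higher and 3 lower of 10, GPI-anchored protein genes 7 higher and 3 lower of 22 (median 0.02, adjusted p = 0.173) and adhesion genes 5 higher and 1 lower of 19 (median 0.09, adjusted p = 0.199). Plasma cell genes had 1 higher and 2 lower of 14 (median -0.24, adjusted p = 0.146), and the monocyte and macrophage list was the last (median 0.31, adjusted p = 0.811). Both comparisons share the arrays of the recipients of knock-out marrow, so they differ in the reference.

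Alternatives other than leaving out arrays also ended calls of genes named between the recipients. With the replicate number as a block Psmb8 (adjusted p = 0.0567), Tap1 (0.0504), Atf3 (0.0689) and Tfrc (0.0732) no longer passed. With only the arrays of the comparison this held for Psmb8 (0.065), Tap1 (0.123), Tfrc (0.0584) and Fkbp11 (0.0957), and with only the arrays of the batch for Tap1 (0.0615). With the mean of a gene's probe sets it held for Psmb8 (0.275), whose other probe set changed in the opposite direction, and for Abcb10 (0.244), Tfrc (0.121) and Mcl1 (0.0561). Blvrb no longer passed with robust estimation (0.0791), Fkbp11 with arrayWeights (0.0527) and Tfrc in eBayes without trend (0.0506).

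The knock-out and transplant comparisons share no array, and their changes can be set side by side. Genes higher in both numbered 301, where independent lists of these sizes would share 82.9, and genes lower in both numbered 196, against 72.5. Opposite changes were found for 66 genes, of which 13 were higher in the knock-out and lower in the recipients and 53 the reverse, against 72.5 and 83. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.305 and a Spearman correlation of 0.101.

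The interaction test called 2707 genes, 1288 more positive and 1419 more negative in the knock-out. With cyclic loess normalization the balance turned to 1548 positive and 1291 negative, and with the mean of a gene's probe sets it was 1106 and 1557. T and NK cell genes had larger rises in the knock-out, with a positive interaction in 22 of 24 cases (22 adjusted over the list alone; median 1.59, adjusted p = 8.48e-18, adjusted p = 0.145 with an estimated correlation). Examples were Cd3e, part of the T-cell receptor complex, at 2.38 ± 0.38 SE, Bcl11b, a T-lineage transcription factor, at 2.30 ± 0.41, and Il7r, the interleukin 7 receptor, at 2.61 ± 0.27 (adjusted p = 9.9e-06). Secondary and tertiary granule genes had a negative interaction in 14 of 17 cases (15 adjusted over the list alone; median -1.18, adjusted p = 5.01e-12, adjusted p = 0.145 with an estimated correlation). B cell genes had a positive interaction in 13 of 23 cases and a negative one for Cr2 and Fcer2a (15 positive and 3 negative adjusted over the list alone; median 0.89, adjusted p = 9.97e-04, adjusted p = 0.5 with an estimated correlation). Igll1 was at 2.37 ± 0.40. Igha, the heavy chain of immunoglobulin A, had the most negative value, -2.89 ± 0.42 (adjusted p = 9e-05), followed by the chemokine gene Cxcl2 at -2.74 ± 0.55. Of the 13 lists past the threshold, 5 positive and 8 negative, none passed with an estimated correlation. Batch, normalization, sex-linked signal, transplantation, aerolysin treatment of donor marrow and the kind of GPI-positive reference all differ between the settings. RNA input also differs if it went with the batches. Hybridisation controls differed by 1.82 log2 between the knock-out fractions and by 0.08 between the recipients. None of these can be told apart in the interaction. With the knock-out GPI-positive arrays averaged, 978 genes were left, and Fos (-2.32 ± 0.59) no longer passed (adjusted p = 0.0761).

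**Figure D3:**
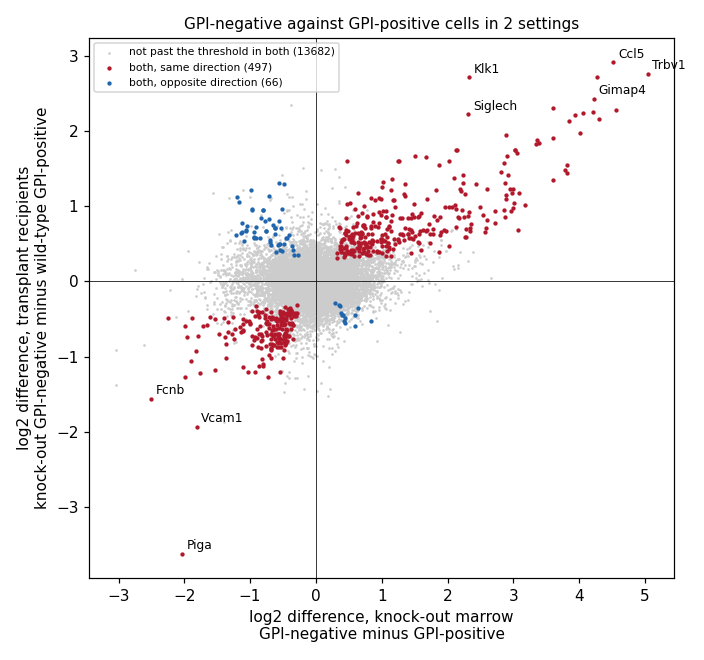
Log2 change of each gene in knock-out marrow (GPI-negative minus GPI-positive) against that between recipients of knock-out and wild-type marrow, 14245 genes. Genes past the threshold in both are coloured by whether the directions match, with 301 higher in both, 196 lower in both and 66 opposite.

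Against untreated wild-type cells, GPI-negative cells of recipients of knock-out marrow had lower erythroid genes, in 20 of 21 cases (20 adjusted over the list alone; median -1.63, adjusted p = 2.11e-22, adjusted p = 0.0848 with an estimated correlation). Rhd fell 4.83-fold (log2 -2.27 ± 0.30 SE, 4 arrays per group), Slc4a1, the anion exchanger of the red cell membrane, 3.9-fold, and Rhag, the Rhesus-associated glycoprotein, 4.15-fold. Heme and iron genes fell in 14 of 18 cases (14 adjusted over the list alone; median -1.05, adjusted p = 1.74e-13, adjusted p = 0.0668 with an estimated correlation). Cpox, an enzyme of heme synthesis, was 2.99-fold lower. Cell cycle genes fell in 21 of 26 cases (22 adjusted over the list alone; median -0.65, adjusted p = 2.62e-21, adjusted p = 0.0848 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell by 1.09 ± 0.15. Vcam1 fell 4.65-fold and C1qa 4.24-fold. The oxidative stress list fell through Nqo1, Gclm, Gclc, Prdx2 and Cat, 5 of 15 (6 adjusted over the list alone; median -0.29, adjusted p = 0.0139, adjusted p = 0.312 with an estimated correlation). Prdx2 is a peroxiredoxin abundant in red cells (-1.33 ± 0.23). Gclm no longer passed without replicate 3 of the recipients (adjusted p = 0.0561) or with robust estimation (0.0536).

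T and NK cell genes rose in this comparison in 20 of 24 cases (22 adjusted over the list alone; median 1.17, adjusted p = 2.28e-21, adjusted p = 0.0668 with an estimated correlation). Dendritic cell genes rose in 11 of 16 cases (12 higher and 1 lower adjusted over the list alone; median 0.57, adjusted p = 1.05e-08, adjusted p = 0.0668 with an estimated correlation). H2-Ab1, an MHC class II chain, was 2.57-fold higher. Of 26 immediate early and heat shock genes 11 rose and Jund fell (13 higher and 1 lower adjusted over the list alone; median 0.36, adjusted p = 9.94e-05, adjusted p = 0.312 with an estimated correlation). The transcription factor Fos was 8.65-fold and Dusp1, a phosphatase of MAP kinases, 3.52-fold higher. Inflammatory mediators rose in 8 of 21 cases (8 adjusted over the list alone; median 0.28, adjusted p = 1.62e-05, adjusted p = 0.115 with an estimated correlation). The neutrophil chemokine Cxcl2 was 5.99-fold and the cytokine Osm 4.49-fold higher. Of 13 eosinophil, basophil and mast cell genes 6 rose, with Fcer1a, the alpha chain of the high-affinity IgE receptor, 5.22-fold, Mcpt8, a basophil protease, 3.96-fold and Cpa3, a mast cell and basophil carboxypeptidase, 3.39-fold higher, while Il5ra fell. That list's call (6 higher and 1 lower adjusted over the list alone; median 0.44, adjusted p = 0.032, adjusted p = 0.419 with an estimated correlation) was lost without replicate 4 of the recipients (0.069) or replicate 1 (0.065) or 2 (0.074) of wild type. MHC class I genes rose in 4 of 12 cases and B2m fell (5 higher and 1 lower adjusted over the list alone; median 0.22, adjusted p = 0.0063, adjusted p = 0.222 with an estimated correlation). B cell genes fell in 6 of 23 cases while Cr2 and Fcer2a rose (9 lower and 2 higher adjusted over the list alone; median -0.27, adjusted p = 0.0063, adjusted p = 0.493 with an estimated correlation). This call was lost without replicate 2 of the recipients (0.13). The unfolded protein response (4 of 20 higher, 4 adjusted over the list alone), ribosomal protein (3 of 19, 3 alone) and apoptosis (3 of 22, 4 higher and 1 lower alone) lists passed with adjusted p of 0.0214, 0.032 and 0.038. The adjusted p was 0.268, 0.419 and 0.419 with an estimated correlation. Their calls were lost without replicate 3 (0.067) or 4 (0.066) of the recipients for the unfolded protein response. The same held without replicate 1 of the recipients (0.21) or of wild type (0.065) for ribosomal proteins, and without replicate 2 of the recipients (0.17) or replicate 3 (0.094) or 4 (0.05, rounded down) of wild type for apoptosis. Monocyte and macrophage genes moved both ways, 11 higher and 9 lower of 23, and did not pass as a list (adjusted p = 0.811).

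In this comparison 1765 of 14245 genes changed, 975 higher and 790 lower, 108 and 116 of them by at least 2-fold. The groups did not overlap for 16.3% of genes, where chance gives 2.86%. The slope of the hybridisation controls was 1.19 ± 0.01 (SD) in the recipients against 1.26 ± 0.03 in wild type, with an exact permutation p of 0.02857, the smallest the design allows. Of 28 lists 14 passed, 9 higher and 5 lower, and none with an estimated correlation.

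Recipients of wild-type marrow differed less from untreated wild type. Interferon-stimulated genes were lower in the recipients, with 6 of 25 past the threshold (16 adjusted over the list alone; median -0.46, adjusted p = 2.76e-16, adjusted p = 0.0932 with an estimated correlation). Oasl2, an antiviral protein related to oligoadenylate synthetases, fell 2.1-fold (log2 -1.07 ± 0.19 SE, 3 and 4 arrays, adjusted p = 0.0087) and Irf9 1.59-fold. Neutrophil primary granule genes rose in 4 of 10 cases, Ctsg, Prtn3, Ms4a3 and Calr (6 adjusted over the list alone; median 0.47, adjusted p = 1.09e-07, adjusted p = 0.0932 with an estimated correlation). Ctsg, which encodes cathepsin G, was 1.61-fold higher. The Ctsg call held without each array in turn. That of Prtn3 was lost without replicate 1 of the recipients (0.0903), that of Ms4a3 without replicate 1 or 2 of either group (0.0842 to 0.143) and that of Calr without any of the 7 arrays (0.0586 to 0.138). The Calr call was also lost with quantile normalization over all arrays (0.0535), the mean of its probe sets (0.106) and the replicate block (0.108), and that of Ms4a3 with only the arrays of the batch (0.0623). In eBayes without trend both were lost (0.0789 and 0.0632). Erythroid genes (2 of 21 lower, 9 adjusted over the list alone; median -0.63) and heme and iron genes (3 of 18 lower, 7 adjusted over the list alone; median -0.45) passed as lists with an adjusted p of 5.46e-08 each. The adjusted p was 0.326 and 0.101 with an estimated correlation. Other changes were Prkcb, protein kinase C beta, 1.96-fold lower (adjusted p = 1.1e-04), Asprv1, an aspartic protease, 2.52-fold lower, and Selenoh, a selenoprotein, and Ift27, a protein of intraflagellar transport, 1.99-fold and 1.86-fold higher. Jchain was 3.93-fold and G0s2, an inhibitor of lipolysis, 2.51-fold higher, and both calls were lost without replicate 1 of the recipients (adjusted p = 0.0641 and 0.0701).

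Lists with small shifts also passed in this comparison. Monocyte and macrophage genes (2 of 23 lower, 8 adjusted over the list alone; median -0.23, adjusted p = 6.89e-06), dendritic cell genes (1 of 16 lower, 3 adjusted over the list alone; median -0.24, adjusted p = 7.83e-04) and complement genes (1 of 15 lower, 3 adjusted over the list alone; median -0.18, adjusted p = 8.73e-04) were lower. Ribosomal protein genes (1 of 19 higher, 6 adjusted over the list alone; median 0.13, adjusted p = 0.00204) were higher. For these 4 lists the adjusted p was 0.22, 0.264, 0.101 and 0.264 with an estimated correlation. B cell genes (1 of 23 lower, 5 adjusted over the list alone; median -0.19, adjusted p = 3e-04), adhesion genes (0 of 19 and 0 adjusted over the list alone, 3 lower at an unadjusted p under 0.05; -0.16, adjusted p = 0.00699) and MHC class I genes (1 of 12 lower, 4 lower and 1 higher adjusted over the list alone; -0.21, adjusted p = 0.016) passed with adjusted p of 0.425, 0.113 and 0.264 with an estimated correlation. Without replicate 1 of the recipients they missed the threshold (0.24, 0.051 and 0.051). T and NK cell genes (median -0.19, adjusted p = 0.0275) and cholesterol synthesis genes (0.16, adjusted p = 0.0492) held no gene past the threshold in limma's fit, and 0 and 1 adjusted over the list alone. At an unadjusted p under 0.05, 3 were lower and 1 higher on the former list, and 5 higher and 1 lower on the latter. Their adjusted p was 0.64 and 0.425 with an estimated correlation. The T and NK cell call was lost without replicate 2 of the recipients (0.086) or replicate 1 of wild type (0.23). The cholesterol call was lost with quantile normalization over all arrays (0.053) and without replicate 3 of the recipients (0.32) or replicate 2 (0.064) or 3 (0.076) of wild type. Eosinophil, basophil and mast cell genes (1 of 13 higher, 4 adjusted over the list alone; median 0.13, adjusted p = 0.016, adjusted p = 0.425 with an estimated correlation) lost the call without replicate 1 (0.051) or 2 (0.086) of the recipients or replicate 2 of wild type (0.064).

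Here 120 of 14245 genes changed, 64 higher and 56 lower in recipients of wild-type marrow, and the groups did not overlap for 13.9% of genes, where chance gives 5.71%. Single arrays weighed heavily on this count. Without replicate 1, 2 or 3 of the recipients it was 21, 55 and 77, and without replicate 1, 2 or 4 of wild type it was 29, 60 and 57. The Actb 3' minus 5' signal was higher in the recipients, 1.26 ± 0.22 (SD, log2) against 0.91 ± 0.10, with an exact permutation p of 0.02857, the smallest the design allows. Of 28 lists 14 passed, 4 higher and 10 lower, and none with an estimated correlation. In all comparisons, the direction of every list past the threshold was the same with quantile and cyclic loess normalization over all arrays, and list median, mean and test differed in sign for none of them.

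Sex-linked genes separated the batches. On its brighter probe set the Y-linked gene Eif2s3y had deposited values of 1.69 to 1.74 on all batch 1 arrays and at most 0.268 in batch 2. Its other probe set was dim and overlapped between batches, at 0.247 to 0.458 in batch 1 and at most 0.331 in batch 2. Xist, the RNA that silences the second X chromosome in female cells, was at 2.228 to 2.462 on all batch 2 arrays on its brightest probe set. Its other probe sets were at 1.702 to 1.956 and 0.548 to 0.779 there. In batch 1 the brightest Xist probe set was at 1.239, 0.501 and 1.647 in knock-out GPI-negative replicates 1, 2 and 3. It was at 0.572, 0.618 and 0.513 in the GPI-positive samples. Replicates 1 and 3 therefore carried Y-linked signal and raised Xist signal together. With the Xist level as a covariate, chosen after seeing the data, 3579 genes changed between the knock-out fractions. Of the 4206 genes called without it, 2949 were among them.

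**Figure D4:**
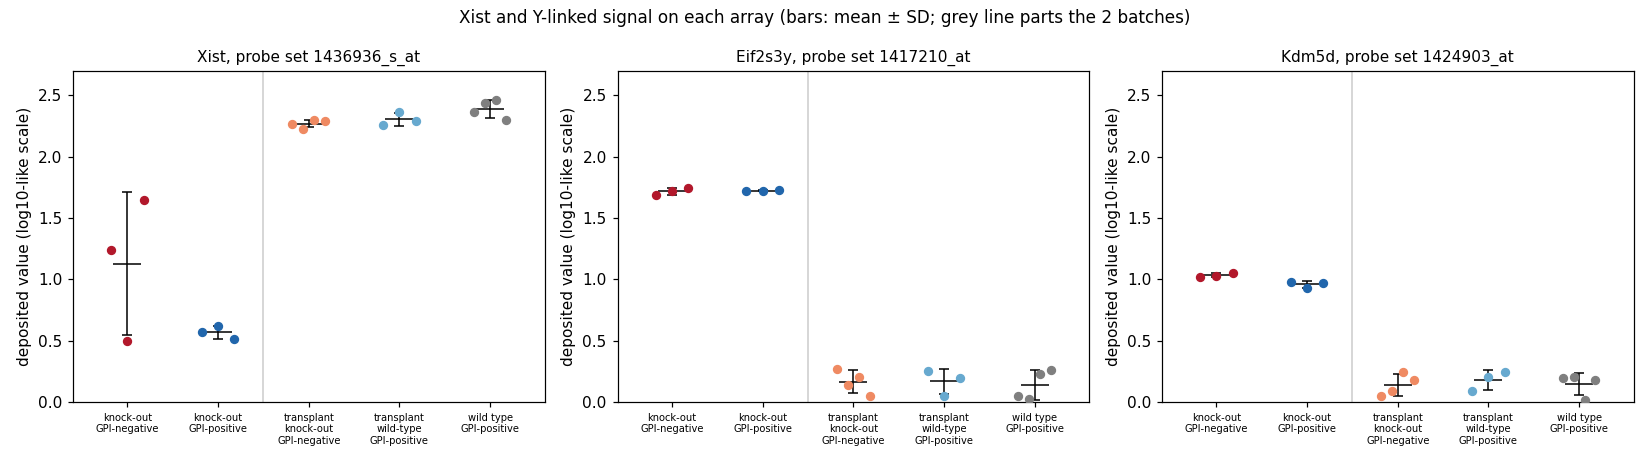
Deposited log10-like values of Xist and the Y-linked genes Eif2s3y and Kdm5d on each array, on the brightest probe set of each gene, by group, with group means and SD. Batch 1 arrays have Eif2s3y at 1.69 to 1.74, and knock-out GPI-negative replicates 1 and 3 also have Xist at 1.239 and 1.647, while batch 2 arrays have Xist from 2.228 to 2.462.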

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

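The tests of the 3 patterns weighed here were chosen only after the results were seen, while the other splits of the arrays were fixed beforehand.

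T and NK cell genes were higher in GPI-negative cells in both settings, against GPI-positive cells stained for CD24, CD48 and Gr-1. CD48 is also carried by lymphocytes and could draw GPI-normal ones into the GPI-positive fraction, but the purity of the fractions was not tested. A lower share of another cell type would raise all remaining types alike. The T and NK list mean exceeded those of cell type lists not called lower by more than 2 SE for 7 of 7 in the knock-out (by 1.99 to 3.10 log2). Among recipients it did so for 7 of 8 (by 1.12 to 1.38), the exception being dendritic cells at 0.40, SE 0.24. A first form had used the erythroid list, which itself fell among recipients. The T and NK list was picked for its rise in these data, and in the knock-out the SE rests partly on the unusually close GPI-positive arrays. The values therefore argue only against an equal rise of all these lists. Cells with intact Piga in the knock-out GPI-negative fraction could not be settled, because the 2 Piga probe sets differed. On the brighter one, the only one read in a first form of this test, Piga fell less in that fraction than among recipients (interaction 1.58, SE 0.22, adjusted p = 6.5e-05). On the second it did not (-0.37, SE 0.29). The value of 1.58 is no bound in either direction, as the recipients' level is at background and the knock-out level is dim. The Piga level remaining was 24.3% (19.3 to 30.6) and 47.1% on the 2 probe sets in the knock-out and 8.14%, an upper bound for that probe set, and 61% among recipients, so it gives no share of intact cells. The knock-out GPI-negative level was dim too, at the 57.1th percentile on the brighter probe set, so the knock-out percentages may also be overstated. Piga on the brighter probe set in recipients of knock-out marrow (0.039 to 0.231, deposited values) lay in the range of the brighter probe set of the Y-linked Eif2s3y on batch 2 arrays (0.022 to 0.268). Levels of different probe sets are not comparable, so this does not show that Piga was absent. With no measured share of T and NK cells, GPI-negative T and NK cells stay open as a biological hypothesis in both settings.

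Knock-out GPI-negative replicates 1 and 3 carried Xist signal beside Y-linked signal. A single cross-hybridising probe set is argued against by 3 of 3 Xist probe sets being higher on both arrays than on the 4 other batch 1 arrays, and a mislabelled female sample by a Y-linked level only 0.02 log2 from the GPI-positive samples. RNA of female cells could not be settled: Y-linked genes on these arrays lay 0.17 (SE 0.11, 4 probe sets) above replicate 2. A first form of this test took female shares of 8.23% and 21.1% from Xist, predicted a change of -0.23 and so counted against female RNA, but its rule was changed after the result was seen, because those shares rest on the Xist level of the separately normalized batch 2. No biological explanation was tested.

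The 3 knock-out GPI-positive arrays lay closer to each other than those of any other group, the lowest ratio of another group's median SD to theirs being 2.18. The GPI-negative arrays normalized with them had a median SD 2.83 times as large, so the closeness was not shared by all batch 1 arrays. For the GPI-positive groups of batch 2 the lower ratio was 2.18, so it was not shared by all sorted GPI-positive cells. Both ratios are part of the pattern itself and so test neither batch 1 normalization nor uniform GPI-positive cells as its source. Whether the 3 arrays are repeat arrays of 1 RNA stays open for the same reason, and the titles call the samples biological replicates.

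Other splits of the same arrays were fitted for each count. For the knock-out comparison the real split gave 4206 genes and the highest other 0, and the 10 splits are too few for a share under 0.05. For the recipients 1 of 35 splits, the real one, gave as many genes as its 1053. The highest other gave 752, from a split that joins replicate 1 of the recipients of knock-out marrow with the recipients of wild-type marrow. The share was also 1 of 35 for recipients of knock-out marrow (1765, highest other 1) and of wild-type marrow (120, highest other 1) against wild type. This is the smallest share that 35 splits allow. It is under 0.05 and argues against chance, but does not exclude it. For the interaction 4 of 100 splits, the real one included, gave as many genes as its 2707, and the highest other gave 3224. The 3 others as large are all among the 14 drawn that keep the knock-out arrays in their groups, and the highest among the rest gave 1. The count therefore reflects mainly the structure of the knock-out arrays, and chance cannot be excluded for the grouping of the transplant arrays.

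The interaction test called 2707 genes. However, batch, normalization, sex-linked signal, aerolysin treatment and the kind of GPI-positive reference differ between the settings, as RNA input may. They cannot be told apart from an effect of the setting. The most positive were Il7r at 2.61, Cd3e at 2.38, Cd2 and Igll1 at 2.37 each, Bcl11b at 2.30 and Cd8b1 at 2.28. The most negative were Igha at -2.89, Cxcl2 at -2.74, Thbs1 at -2.43, Igkv9-120 at -2.35, and Wfdc17 and Fos at -2.32 each. List medians were 1.59 for T and NK cells, 0.89 for B cells, 0.87 for erythroid, 0.39 for cell cycle and 0.36 for ribosomal protein genes. Negative medians were -1.18 for secondary and tertiary granule, -1 for eosinophil, basophil and mast cell, -0.78 for primary granule, -0.72 for monocyte and macrophage and for inflammatory, -0.70 for immediate early, -0.54 for complement and -0.22 for GPI-anchored protein genes. The last of these missed the threshold with quantile normalization (adjusted p = 0.073), with the replicate number as a block (0.072), and without replicate 3 of knock-out GPI-negative (0.081), 2 (0.052) or 3 (0.065) of knock-out GPI-positive, or 1 (0.095) or 4 (0.067) of the recipients of knock-out marrow. The cell cycle and immediate early calls were lost without knock-out GPI-negative replicate 2 (0.057 and 0.079).

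Control probes outside the gene comparisons differed between groups. Hybridisation controls were higher by 1.82 log2 in knock-out GPI-negative than GPI-positive samples and the Gapdh 3' minus 5' signal by 0.85, and the Actb 3' minus 5' signal by 0.34 in recipients of wild-type marrow against wild type. The slope of the hybridisation controls on log10 concentration differed by -0.20 between knock-out GPI-negative and GPI-positive samples and by -0.07 between recipients of knock-out marrow and wild type.

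Of 538 group values tested, 27 had 1 array far from the 3 others, and chance gives about 1 in 20. Of these, 21 were gene values, 4 list means and 2 array measures, with 12 in recipients of knock-out marrow and 15 in wild type. In log2 units, wild-type replicate 1 was apart for Klk1 (2.79), Ngp (10.73), Nr4a1 (2.71) and Rpl11 (8.13), and wild-type replicate 2 for Acaca (2.48), Cpa3 (3.38), Ermap (5.41), Flt3 (2.25) and Wfdc21 (8.51). Wild-type replicate 3 was apart for Igkv15-103 (2.1), Siglech (2.41) and the MHC class I list mean (5.98), and replicate 4 for S100a9 (12.48), Slc40a1 (6.47) and the Gapdh 3' minus 5' signal (-0.84). In recipients of knock-out marrow, replicate 1 was apart for Alad (4.87), Birc5 (5.78), Tfrc (6.69) and the list means of secondary and tertiary granule (9.14) and ribosomal protein genes (9.11). Replicate 2 was apart for S100a9 (12.2) and Zmat3 (1.71), replicate 3 for Sowaha (0.98) and the slope of the hybridisation controls (1.18), and replicate 4 for Cd14 (3.57), Tnfrsf17 (0.77) and the MHC class I list mean (6.41).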

How the results depend on the processing

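Averaging the 3 knock-out GPI-positive arrays, the Xist covariate and leaving out the cell type lists were chosen after the data were seen, and the other alternatives beforehand. Of the values for single lists, 1757 kept direction and side of the threshold, 35 newly passed it, 112 no longer did and 0 reversed. Of those for named genes, 6986 kept both, 89 newly passed, 345 no longer did and 2 reversed, Fkbp11 between recipients (0.061) and Hspa5 against wild type (-0.018), each with the mean of a gene's probe sets. Of the counts and Piga values, 244 were labelled the same and 31 moved, a count being moved beyond a ratio of 1.5. The label did not weigh the size of Piga changes. On the second Piga probe set the log2 change was -0.713 between recipients and -0.865 against wild type, where the main values were -3.619 and -3.693, and both were labelled the same. Testing all probe sets separately, which tests more features, gave 8239 in the knock-out, 2648 and 200 for recipients of knock-out and wild-type marrow against wild type, and 4849 in the interaction. The 2-fold threshold, stricter by construction, gave 749, 142, 224 and 16 in the 4 comparisons and 785 in the interaction. The comparison of recipients of wild-type marrow with wild type also moved to 237 with its own arrays only, 59 without trend, 353 with arrayWeights, 45 with the replicate block and 299 at an adjusted p of 0.1. With the knock-out GPI-positive arrays averaged, which leaves fewer samples and 1 lone sample assumed to vary like the other groups, 1652 genes changed in the knock-out and 978 in the interaction, and 206 were higher and 77 lower in both settings. Leaving out 1 array in turn gave 3298 to 3901 genes in the knock-out, 680 to 1310 between recipients, 1315 to 1729 for recipients of knock-out marrow and 21 to 89 for recipients of wild-type marrow against wild type, and 2095 to 3064 in the interaction. Lists past the threshold with an estimated correlation were 1, 8, 0 and 0 in the 4 comparisons and 0 in the interaction. With fry they were 15, 14, 16 and 6, and 11 in the interaction, though not always the same lists. The main test passed 11, 15, 14 and 14, and 13 in the interaction. Apart from the changes in fitted features, samples or threshold, the cause was not tested. Deviations of arrays with the same replicate number correlated at -0.18 to 0.1. The own number was the best partner only for replicates 1 and 2 of recipients of wild-type marrow. With so few arrays per group this shows no pairing but cannot exclude it. As a block the replicate numbers gave 3942, 807, 1524 and 2197 in the comparisons other than the 45 above. Pseudocounts and the sex covariate were not run. Signal near the floor limits dim genes such as Piga in recipients of knock-out marrow.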

Other observations

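The tests of gene families named by a shared symbol stem, 236 in all, were chosen only after the data were seen.

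The Gimap family, GTPases of lymphocytes, was higher in GPI-negative cells throughout. All 8 tested members rose in knock-out marrow (median log2 change 2.89, camera adjusted p = 1.4e-12, adjusted p = 0.34 with an estimated correlation), 7 rose among recipients (1.39, adjusted p = 8.1e-13, adjusted p = 0.32 with an estimated correlation) and 6 in recipients of knock-out marrow against wild type (1.13, adjusted p = 1.1e-06, adjusted p = 0.82 with an estimated correlation). Immunoglobulin kappa variable genes (Igkv) fell in 8 of 11 cases in knock-out marrow (median -1.13, adjusted p = 0.0039, adjusted p = 0.34 with an estimated correlation). Among recipients, Mcm genes, most of which encode parts of the replicative helicase, fell in 5 of 10 cases (-0.43, adjusted p = 1.3e-05, adjusted p = 0.47 with an estimated correlation). The interferon-induced Ifi genes rose in 4 of 11 cases (0.46, adjusted p = 4.9e-05), the Toll-like receptor genes in 4 of 10 (0.35, adjusted p = 0.012) and the interferon regulatory factor genes in 4 of 11 (0.33, adjusted p = 0.016), each with an adjusted p of 0.47 with an estimated correlation.

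In recipients of wild-type marrow against wild type, genes of mitochondrial ribosomal proteins shifted upward by small amounts, Mrpl genes with a median of 0.19 (1 of 47 rose, adjusted p = 9.2e-05, adjusted p = 0.79 with an estimated correlation) and Mrps genes with 0.17 (2 of 29 rose, adjusted p = 1.8e-05, adjusted p = 0.79 with an estimated correlation). Between the recipients, where the same arrays are the reference, the medians were -0.16 for Mrpl (adjusted p = 0.0039) and -0.13 for Mrps genes (adjusted p = 0.035), each with an adjusted p of 0.81 with an estimated correlation. Ifi and Gimap genes, higher between the recipients, were likewise lower in recipients of wild-type marrow than in wild type, with medians of -0.24 (adjusted p = 0.018) and -0.26 (adjusted p = 0.042), each with an adjusted p of 0.79 with an estimated correlation. The directions of these families were the same with quantile and cyclic loess normalization over all arrays.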
